A study of Homo sapiens with 16 samples.

How the data were processed

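ATAC-seq libraries of Rh30 cells with FKBP-tagged PAX3-FOXO1 were analysed from the authors' deposited tables, 2 count tables and 6 comparison tables, 1 count table for each experiment and 1 comparison table for each of the 6 comparisons with DMSO. The submitters' processing notes name Trimmomatic 0.32, Bowtie2, Genrich 0.6.1, DiffBind, DESeq2 and deepTools, with the builds hg19 and dm3, without saying which step used which. Coordinates are those of the deposited tables and are taken as hg19 from the human build in those notes. Whether reads were shifted for the transposase, how duplicates and mitochondrial reads were treated and how the peaks were merged is not given in the sources used here. The deposited count tables hold raw read counts per consensus region, whole numbers with a different total in each library. Regions of experiment 6086 had a median width of 320 bp (74 to 9858 bp), while 97.8% of those of 6211 were 401 bp wide, so levels in CPM are not comparable between the tables. The deposited comparison tables also hold size-factor-normalised counts (a signal column per library, per the file headers), which were checked to equal the raw counts divided by 1 constant per library and were otherwise used only for that check. Log2 fold changes and p-values in the authors' tables come from a DESeq2-style test, per the file headers, and were used only for comparison with the tests made here.

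Columns were assigned to groups by treatment and time in their names. The letters A and B in the column names could not be tied to the replicate numbers of the labels, so they serve as names of libraries and, in 1 alternative, as a block. No per-library column lay outside the 2 experiments' groups. The chi-square of the counts of each replicate pair was 1.34 to 2.66 per degree of freedom, so no pair agreed within sampling noise.

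Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalisation, filterByExpr, quasi-likelihood fit and test, group means), with all 8 libraries of an experiment in 1 fit and 4 residual degrees of freedom. The filter left 56945 of 56949 regions in 6086 and all 40844 in 6211. Calls were made at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. The biological coefficient of variation was 3.48% in 6086 and 5.96% in 6211. The median log2 change over all regions lay between -0.0031 and 0.0092 in each comparison, near the 0 that TMM assumes while a uniform change of accessibility across all regions would not be seen.

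On simulated counts drawn from the means and library sizes of the real data, with 200 regions changed, the 2 h test in 6086 (56944 regions) recovered 28% of 1.25-fold, 82% of 1.5-fold, 100% of 2-fold and 98% of 3-fold changes with 12 false calls. In 6211 (40844 regions) it recovered 10%, 64%, 96% and 100% with 5 false calls. Most 1.25-fold and some 1.5-fold changes were thus missed in these simulations. Recovery may differ in the real data, where far more than 200 regions were called at 2 h. Of the 2975 regions called at 2 h in 6086, only 194 lower and 2 higher ones changed at least 2-fold, so smaller changes were also called.

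Named regions were chosen by a rule fixed before the data were examined: among regions past the threshold with a mean count of at least 30 and both treated libraries on the same side of both DMSO libraries in log-CPM (prior count 2), the 3 lowest and the 3 highest log2 fold changes of each comparison with DMSO. That rule applied where no annotation could be used, and regions named outside it are said to be. The design also held 12 gene lists, a promoter and distal split and sequence motifs. These were not tested, because no genome or annotation on hg19 was used here and coordinates were not converted.

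The labels give no duration for DMSO, and each experiment had 1 DMSO group for all times. Replicates are not said to be separate cultures, so p-values measure only the spread between libraries of the same group. The fit pooled this spread over the groups of an experiment and drew it toward that of other regions (prior degrees of freedom 29.9 in 6086 and 19.6 in 6211). Regions of the 2 experiments were matched with bedtools 2.31.1 by 50% reciprocal overlap, keeping pairs in which each region had a single partner. Difference between the 2 h effects was tested as an interaction in 1 edgeR fit over matched regions, with TMM within each experiment. Correlations and covariances expected from shared DMSO libraries came from 20 simulations of unchanged groups. Clustering along the genome was tested with 1000 random sets drawn within deciles of abundance, using Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and checked on a random and a planted set.

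Alternatives fixed before the data were examined were DESeq2 1.42.0 in place of edgeR, library size only, median-ratio size factors, TMM on the upper 25% of regions by mean count, a loess offset (limma 3.58.1), no filter, a mean count of at least 50, only the groups compared, and each library left out in turn. Matching by 1 bp and by 80% reciprocal overlap was fixed in the same way. Added after seeing the data were the library letter as a block, DMSO libraries split between comparisons, libraries thinned to the lowest total, distances of 5 and 50 kb for neighbouring regions, the counts without a stretch of chromosome 12, the loess offset and left-out libraries for the comparison of the 2 h effects, and every alternative of the regions followed across experiments.

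In the authors' deposited tables, 1398 (6086, 2 h), 2103 (4 h) and 11323 (24 h) regions and 2 (6211, 0.5 h), 366 (1 h) and 1341 (2 h) regions had an adjusted p under 0.05. DESeq2, as run here on the counts, called the same numbers, and every region called in the authors' deposited tables was also called in the same direction by edgeR.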

Results

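Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in Rh30 cells. Rh30 is an established human cell line from an alveolar rhabdomyosarcoma, a childhood muscle-lineage tumour, and it carries the PAX3-FOXO1 fusion, a transcription factor that drives this tumour type. In the cells used here the fusion carried an FKBP tag, so that dTAG47, a degrader molecule that joins FKBP-tagged proteins to a ubiquitin ligase, could remove it. The design asked which open regions depend on the fusion and how soon accessibility changes once it is degraded. All libraries came from tagged cells, and the level of the fusion was not analysed here. Losing the fusion thus cannot be told apart from other effects of dTAG47, and times are hours of dTAG47.

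Cells received DMSO or 500 nM dTAG47 in 2 separate experiments, called 6086 and 6211 after the labels. Experiment 6211 covered 0.5, 1 and 2 h of dTAG47 and experiment 6086 covered 2, 4 and 24 h, each with its own DMSO group. Every group had 2 libraries, giving 16 libraries in all. Reads were counted over 40844 regions in experiment 6211 and 56949 regions in experiment 6086. Libraries held between 9934147 and 18275976 reads in regions in 6211, and between 18038062 and 31308682 in 6086. Replicate libraries had Spearman correlations across regions of 0.960 to 0.976 in 6211 and of 0.987 to 0.992 in 6086. Regions are named by position on hg19 because no gene annotation of that build was used here. The largest losses and gains named are those among regions past the threshold with a mean count of at least 30 and treated libraries both on the same side of the DMSO libraries. Levels are given as CPM, read counts scaled by the TMM-adjusted number of reads in regions, as mean ± SD of the 2 libraries of a group, and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The labels do not say that replicate libraries came from separate cultures, so the p-values measure only the spread between libraries, which may be technical.

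After 0.5 h of dTAG47, 3 of the 40844 regions fell and 0 rose. On chromosome 6, the region at 44628192 to 44628592 dropped from 62.2 ± 0.213 CPM to 40.9 ± 2.12 CPM (SD, n = 2), a log2 change of -0.61 (SE 0.08, adjusted p = 0.0086). The other two were 1:36071004-36071404, from 53.3 ± 2.83 to 33.9 ± 2.46 CPM (log2 change -0.65, SE 0.10, adjusted p = 0.015), and 7:25817794-25818194, from 38.0 ± 1.57 to 24.2 ± 0.386 CPM (log2 change -0.66, SE 0.10, adjusted p = 0.026). All 3 had fallen further by 2 h, to log2 changes of -1.80, -1.71 and -1.31. In edgeR, 2723 regions had an unadjusted p under 0.05, and DESeq2 called 2 regions lower and 0 higher. The count rested on single libraries: it was 0 without DMSO library A or without either 0.5 h library, 214 (105 lower, 109 higher) without DMSO library B, 6 with a loess offset and 10 with only the groups compared in the fit.

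At 1 h, 1010 regions had fallen and 90 had risen. Among the lower regions, 44 had lost at least 2-fold, and no higher region had gained that much. Accessibility at 1:235344260-235344660 dropped from 15.2 ± 4.28 to 5.73 ± 1.73 CPM (log2 change -1.45, SE 0.20, adjusted p = 0.00017). It also fell at 2:229391074-229391474, where DMSO had 18.2 ± 0.886 CPM (log2 change -1.36, SE 0.14, adjusted p = 2.2e-05), and at 18:1017212-1017612, from 13.7 ± 1.27 to 5.57 ± 0.584 CPM (log2 change -1.28, SE 0.16, adjusted p = 5.0e-05). The highest gain was at 17:79008491-79008891, from 11.1 ± 0.777 to 18.8 ± 3.26 CPM (log2 change 0.77, SE 0.14, adjusted p = 0.0022). At 5:177190713-177191483 the log2 change was 0.71 (SE 0.18, adjusted p = 0.028) and at 17:17585060-17585460 it was 0.70 (SE 0.18, adjusted p = 0.031). These 2 regions were not past the threshold at 2 h, where their log2 changes were 0.53 (adjusted p = 0.097) and 0.21 (adjusted p = 0.60). Without 1 h library B none of the 3 gains passed (adjusted p = 0.13, 0.80 and 0.58), and the latter 2 also missed it without DMSO library A (0.36 for both) and in DESeq2 (0.59 and 0.21). The 1010 lower and 90 higher regions became 616 and 12 with only the groups compared in the fit, 326 and 6 without DMSO library A, 1592 and 967 without DMSO library B, 1316 and 331 without 1 h library A and 172 and 2 without 1 h library B. DESeq2 called 360 regions lower and 6 higher.

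By 2 h in experiment 6211, 2009 regions had fallen and 806 had risen, 258 and 32 of them by at least 2-fold. The median log2 change was -0.60 over the lower regions and 0.49 over the higher ones. The deepest loss was again at 1:235344260-235344660, now at 3.27 ± 1.03 CPM against 15.2 ± 4.28 CPM in DMSO (log2 change -2.25, SE 0.24, adjusted p = 9.5e-07). At 12:66997804-66998204 the level dropped from 19.9 ± 1.19 to 5.10 ± 0.983 CPM (log2 change -1.98, SE 0.17, adjusted p = 3.5e-08), and at 5:170008193-170008593 from 22.1 ± 1.41 to 5.64 ± 0.917 CPM (log2 change -1.97, SE 0.16, adjusted p = 3.2e-08).

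The 3 regions with the highest gain at 2 h in experiment 6211 all lay on chromosome 12: 57539061 to 57539461 (log2 change 1.41, SE 0.23, adjusted p = 0.00027), 57869376 to 57869776 (1.33, SE 0.26, adjusted p = 0.0018) and 57554676 to 57555076 (1.27, SE 0.22, adjusted p = 0.00046). The first went from 11.7 ± 3.86 to 30.8 ± 12.8 CPM. They belong to a stretch from 57 to 59 Mb that held 125 of the 806 higher regions (15.5%) among 250 tested regions (0.612% of all). Without 2 h library B 19 higher regions lay there, and without DMSO library A 46. No other 1 Mb window held more than 11. Replicate libraries differed over this stretch as well: the median region was 0.25 higher on the log2 scale in DMSO library B than in DMSO library A, and 0.25 higher in 2 h library B than in 2 h library A. Of 163 runs of 250 neighbouring regions, 0 differed that far between replicates of either group. Without the stretch, 681 higher and 2007 lower regions remained. Outside it, and chosen after the values were seen, the highest gains were at 16:46391136-46391536 (log2 change 1.14), 17:22253012-22253412 (1.10) and 5:34191381-34191781 (1.09). Their replicates lay far apart, with 4.33 ± 1.73 to 9.41 ± 2.78, 4.30 ± 2.31 to 8.99 ± 2.67 and 10.2 ± 3.38 to 21.7 ± 8.62 CPM (adjusted p = 0.0039, 0.013 and 0.0036). None of the 3 gains in the stretch was called by DESeq2 (adjusted p = 0.073, 0.26 and 0.094), and the second was also lost without 2 h library B (adjusted p = 0.11). DESeq2 called 1186 regions lower and 155 higher at 2 h, so the lower share of calls was 88.4% against 71.4% with edgeR. The 806 higher regions became 195 without DMSO library A, 504 without 2 h library A, 109 without 2 h library B and 418 with only the groups compared in the fit, while the 2009 lower ones became 1292, 1505, 1119 and 1588.

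**Figure D1:**
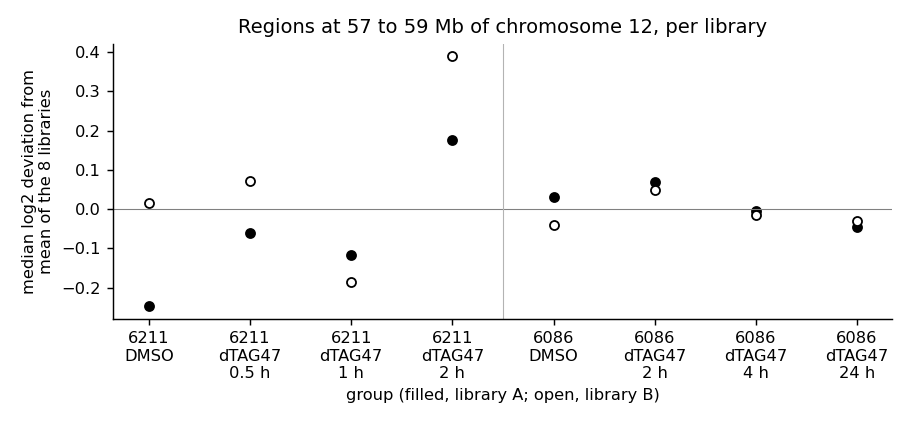
Median log2 deviation of each library from the mean of the 8 libraries of its experiment, over the tested regions at 57 to 59 Mb of chromosome 12 (250 in 6211, 213 in 6086), with the groups on the horizontal axis, library A filled and library B open. In 6211 the libraries run from -0.25 to 0.39, with the DMSO and 2 h replicates furthest apart, while in 6086 they lie between -0.04 and 0.07.

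Between 0.5 and 2 h, tested directly, 521 regions fell and 60 rose in experiment 6211. The region 12:66997804-66998204 lost a further 1.47 on the log2 scale (log2 change -1.47, adjusted p = 3.0e-05), and 5:170008193-170008593 a further 1.32 (log2 change -1.32, adjusted p = 0.00011). The 521 lower and 60 higher regions became 137 and 0 without 0.5 h library A, 107 and 2 without 0.5 h library B, 525 and 123 without 2 h library A, 154 and 1 without 2 h library B, and 993 and 252 with only the groups compared in the fit. Without the chromosome 12 stretch the higher count was 26. DESeq2 called 236 regions lower and 6 higher in this comparison.

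In the second series of time points, experiment 6086, 2418 regions had fallen and 557 had risen after 2 h. The lower regions had a median log2 change of -0.51 and 194 of them lost at least 2-fold, whereas the higher ones had a median of 0.34 and 2 of them gained that much. At 20:40621138-40621554 accessibility dropped from 13.7 ± 0.245 to 3.37 ± 0.166 CPM (log2 change -2.02, SE 0.12, adjusted p = 6.1e-14). At 15:57944755-57944919 it dropped from 5.93 ± 0.252 to 1.57 ± 0.0486 CPM (log2 change -1.91, SE 0.18, adjusted p = 1.3e-09), and at 4:80076611-80076799 from 6.34 ± 1.33 to 1.70 ± 0.168 CPM (log2 change -1.87, SE 0.19, adjusted p = 5.0e-09). The highest gains were in narrow regions with few reads: 1:46259730-46259844 (0.753 ± 0.124 to 1.65 ± 0.00960 CPM, log2 change 1.16, adjusted p = 0.0094), X:23522098-23522192 (0.697 ± 0.0447 to 1.36 ± 0.0723 CPM, log2 change 0.97, adjusted p = 0.048) and 2:26947472-26947586 (1.78 ± 0.0228 to 3.43 ± 0.515 CPM, log2 change 0.95, adjusted p = 0.0011). DESeq2 called 1328 regions lower and 70 higher, a lower share of 95.0% against 81.3% with edgeR, and it called neither 1:46259730-46259844 (adjusted p = 0.20) nor X:23522098-23522192 (adjusted p = 0.47). The first of these gains was also lost without DMSO library B or either 2 h library (adjusted p = 0.12, 0.082 and 0.061), the second without any 1 of the 4 libraries (adjusted p from 0.12 to 0.27), and the gain on chromosome 2 without 2 h library B (adjusted p = 0.057). The 557 higher regions became 347 without DMSO library A, 941 without DMSO library B, 150 without 2 h library A, 217 without 2 h library B and 322 with only the groups compared in the fit, while the 2418 lower ones became 1767, 2761, 1410, 1779 and 2205.

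At 4 h, 3099 regions had fallen, 396 of them by at least 2-fold, and 995 had risen, 2 of them by that much. The region 5:170008229-170008611 went from 14.1 ± 1.75 to 2.08 ± 0.115 CPM (log2 change -2.74, SE 0.14, adjusted p = 5.3e-16), a 6.70-fold loss. At 20:40621138-40621554 the loss reached a log2 change of -2.48 (SE 0.13, adjusted p = 5.5e-16), and at 11:64297123-64297526 it was -2.44 (16.1 ± 1.05 to 2.97 ± 0.407 CPM, SE 0.13, adjusted p = 4.9e-16). Gains were led by 10:81243917-81244072 (1.49 ± 0.343 to 3.22 ± 0.657 CPM, log2 change 1.14, adjusted p = 0.00026), X:23522098-23522192 (log2 change 1.03, adjusted p = 0.023) and 4:624304-624487 (2.74 ± 0.396 to 5.34 ± 0.191 CPM, log2 change 0.98, adjusted p = 2.0e-05). DESeq2 called 1917 lower and 186 higher regions, a lower share of 91.2% against 75.7%. The gain on chromosome X was lost in DESeq2 (adjusted p = 0.31) and without any 1 of the 4 libraries (adjusted p from 0.062 to 0.17). The 995 higher regions became 324 without 4 h library A, 395 without 4 h library B and 626 with only the groups compared in the fit, while the 3099 lower ones became 2410, 1936 and 2933.

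After 24 h the change was far wider and went both ways: 10611 regions had fallen and 7742 had risen, together 32.2% of the 56945 regions tested. Losses of at least 2-fold numbered 1109, and gains of at least 2-fold numbered 248. The region 5:170008229-170008611 was down to 0.889 ± 0.0918 CPM, a 15.6-fold loss (log2 change -3.97, SE 0.16, adjusted p = 1.2e-19). At 12:66508913-66509375 the level dropped from 14.0 ± 0.201 to 1.22 ± 0.105 CPM (log2 change -3.51, SE 0.14, adjusted p = 1.5e-19), and at 6:44628171-44628686 from 40.4 ± 2.89 to 3.98 ± 0.515 CPM (log2 change -3.34, SE 0.10, adjusted p = 6.8e-23). This last region overlaps 6:44628192-44628592, which had already fallen at 0.5 h in the other experiment. Accessibility rose 4.63-fold at 16:46952967-46953101, from 1.12 ± 0.314 to 5.03 ± 0.00483 CPM (log2 change 2.21, SE 0.20, adjusted p = 5.9e-11). It rose 3.88-fold at 6:30647972-30648148 (log2 change 1.95, SE 0.18, adjusted p = 6.3e-11) and 3.40-fold at 10:50282988-50283348, from 3.34 ± 0.0255 to 11.4 ± 1.05 CPM (log2 change 1.77, SE 0.13, adjusted p = 2.9e-13). DESeq2 called 7125 lower and 4198 higher regions.

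**Figure D2:**
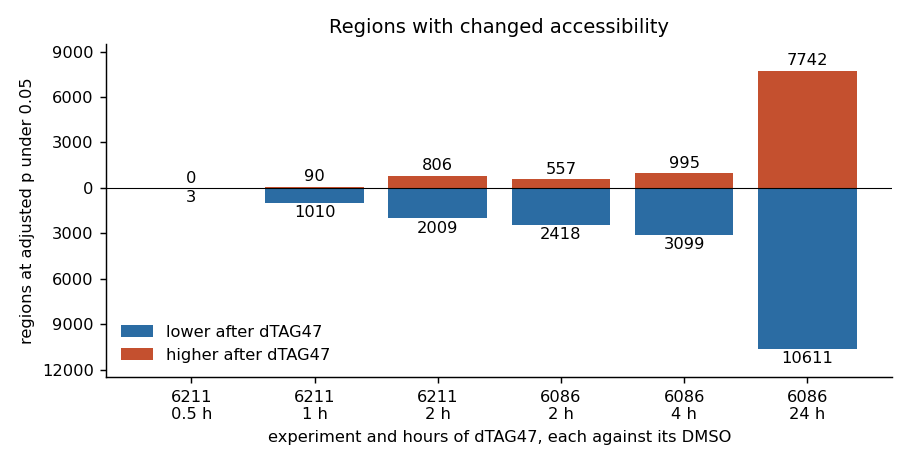
Number of regions at an adjusted p under 0.05 against DMSO (vertical axis; lower regions drawn downward in blue, higher regions upward in orange) for each experiment and time. Counts run from 3 lower and 0 higher regions at 0.5 h to 10611 lower and 7742 higher at 24 h.

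The 24 h effect was compared with the 2 h effect directly in experiment 6086. Between these times 10020 regions fell and 7276 rose. At 5:170008229-170008611 the further log2 change was -2.15 (adjusted p = 8.2e-10), and at 6:44628171-44628686 it was -1.68 (adjusted p = 7.0e-13). The gains at 6:30647972-30648148 and 10:50282988-50283348 arose after 2 h, with further log2 changes of 1.78 (adjusted p = 3.6e-10) and 1.74 (adjusted p = 1.1e-12), since their 2 h changes were 0.17 (adjusted p = 0.80) and 0.03 (adjusted p = 0.96). By contrast, 20:40621138-40621554 lost most of its accessibility by 2 h, and its further change of -0.29 was not past the threshold (adjusted p = 0.18). Of the 10611 regions lower at 24 h, 7665 (72.2%) were also lower than at 2 h, and 6710 of these had not been called at 2 h. Of the 7742 higher at 24 h, 5214 (67.3%) were also higher than at 2 h, and 5138 of these had not been called at 2 h. Both comparisons use the same 24 h libraries, so part of the 72.2% and 67.3% may come from that choice of regions. DESeq2 called 6366 lower and 3328 higher regions in this comparison, and the higher count was 4531 without 2 h library A and 4764 without 24 h library B.

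**Figure D3:**
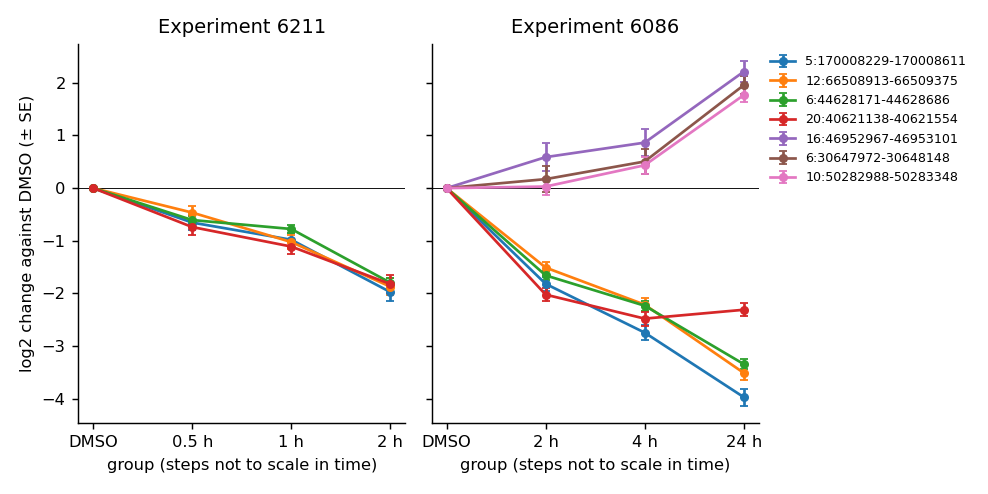
Log2 change against DMSO with its SE (vertical axis) by group in experiment 6211 (left) and experiment 6086 (right) for the 3 regions with the largest loss at 24 h, the region with the largest loss at 2 h in 6086 and the 3 with the largest gain at 24 h. The 4 losing regions lie between -1.80 and -1.97 at 2 h in 6211, and 5:170008229-170008611 reaches -3.97 at 24 h in 6086; the gaining regions had no matched region in 6211.

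Both experiments included 2 h of dTAG47, so that effect could be compared across independent DMSO groups. Of the regions, 29639 could be matched between the tables by 50% reciprocal overlap. Across these matched regions the 2 h log2 changes had a Pearson r of 0.712 and a Spearman rho of 0.524 (regions are not independent replicates). Among 1606 matched regions lower in 6086 and 1496 lower in 6211, 1114 were lower in both, where independent lists would share 81.1. Among 345 higher in 6086 and 569 higher in 6211, 85 were higher in both, against 6.62 for independent lists. Those 85 became 25 without 6211 DMSO library A, 54 and 20 without 6211 2 h libraries A and B, and 19 and 40, of 89 and 121 higher in 6086, without 6086 2 h libraries A and B and 53 of 192 without 6086 DMSO library A. The 1114 became 742 without 6211 DMSO library A. Of the regions lower in 6086, 99.5% had a negative change in 6211, and of those higher in 6086, 95.1% had a positive change there. No region was called in opposite directions. A test of the difference between the 2 effects in edgeR called 0 of the 29639 regions, with 1539 at an unadjusted p under 0.05, and on simulated data the same test recovered 93% of regions with a 2-fold difference. Smaller differences were not simulated, while the matched regions higher in 6086 had a median log2 change of only 0.33 there. The 0 calls thus do not show that gains were equal in the 2 experiments.

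**Figure D4:**
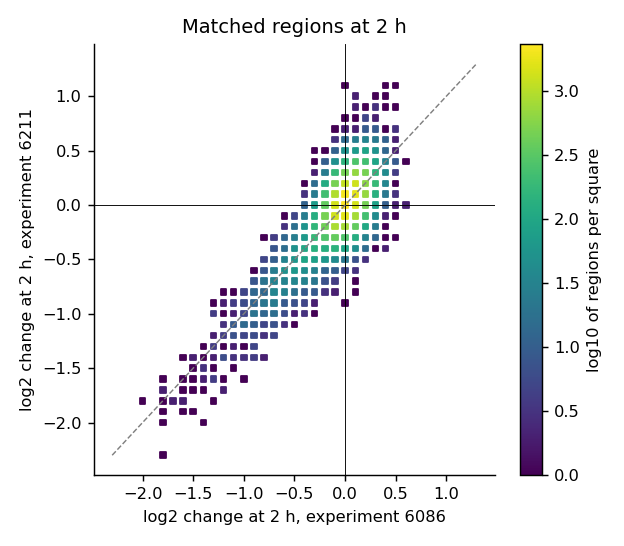
Log2 change at 2 h in experiment 6086 (horizontal) against experiment 6211 (vertical) for the 29639 matched regions, each square covering 0.1 by 0.1 log2 units and coloured by the log10 of the number of regions in it; the dashed line marks equal change. Pearson r was 0.712, and the losing arm lies along the line.

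Regions called in one experiment were followed through the times of the other, which shares no control library with it. The 1606 regions lower at 2 h in 6086 had median log2 changes of -0.23 at 0.5 h, -0.38 at 1 h and -0.54 at 2 h in 6211, and 96.0% of them were already below DMSO at 0.5 h, although 2 of them passed the threshold there. The mean of library medians was -0.23 ± 0.01 at 0.5 h and -0.53 ± 0.01 at 2 h (SD, n = 2), and the medians of the 2 DMSO libraries around their own mean had an SD of 0.07. The 345 regions higher at 2 h in 6086 had medians of 0.09, 0.17 and 0.28 at 0.5, 1 and 2 h in 6211. Of them 82.3% were above DMSO at 0.5 h, and 0 passed the threshold there. The 1496 regions lower at 2 h in 6211 had medians of -0.48, -0.60 and -0.70 at 2, 4 and 24 h in 6086, where 1114, 1205 and 1237 of them were called lower. The 569 regions higher at 2 h in 6211 took another course: their medians were 0.17, 0.12 and 0.01 at 2, 4 and 24 h, with library medians of 0.18 ± 0.03 at 2 h and 0.01 ± 0.02 at 24 h. The 24 h median was 0.09 without 6211 2 h library B, 0.05 without 6211 DMSO library A and 0.07 with DESeq2, in sets of regions chosen again each time. At 24 h, 160 of these 569 (28.1%) were called higher than DMSO and 133 (23.4%) lower. Of all 29639 matched regions, 3593 were higher and 6897 lower at 24 h. The 569 were thus more often higher than matched regions at large, and about as often lower. Gains chosen at 1 h in 6211, 65 matched regions, had medians of 0.15, 0.11 and 0.11 at 2, 4 and 24 h in 6086. At 24 h, 23 of these 65 were called higher and 8 lower, so their median did not return to DMSO. Tested directly between 24 and 2 h, 247 of the 569 gains (43.4%) went back down and 85 went further up, while 128 of the 1496 losses (8.56%) went back up and 664 went further down (Fisher's exact test of the shares going back, two-sided, odds ratio 8.20, p = 6.5e-68, regions not being independent). Falls were about as common in both sets, at 43.4% of the gains and 44.4% of the losses. Over all 56945 tested regions 10020 fell and 7276 rose between these times. The Fisher test sets falls of gains against rises of losses, so it cannot tell a return of gains from a fall common to both sets.

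**Figure D5:**
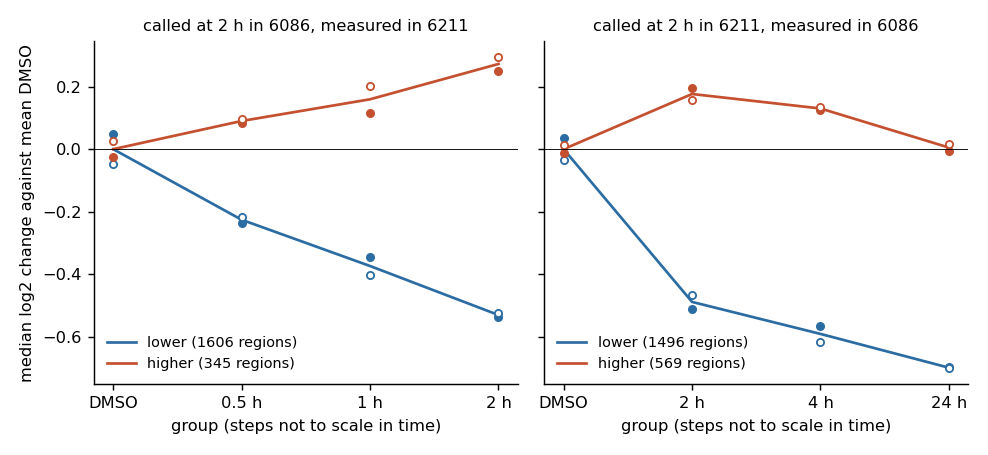
Median log2 change against the mean of DMSO (vertical axis) by group for regions called at 2 h in 6086 and measured in 6211 (left) and called at 2 h in 6211 and measured in 6086 (right); lines join the means of the 2 libraries, filled circles are library A and open circles library B. In 6086 the losses deepen to -0.70 at 24 h and the gains run from 0.18 at 2 h to 0.01 at 24 h.

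Regions called at 2 h in experiment 6086 were also followed within that experiment. Of the 2418 regions lower at 2 h, 2086 were also lower at 4 h (independent lists would share 131.6), 2072 at 24 h (450.6) and 1933 at all 3 times. Of the 557 higher at 2 h, 224 were also higher at 4 h (9.73) and 236 at 24 h (75.7), while 102 were lower than DMSO at 24 h. Over all 56945 tested regions 10611 were lower at 24 h, a share close to that of the 102 of 557. Gains at 4 h lasted more often: of those 995 regions, 751 were also higher at 24 h (135.3 for independent lists) and 18 were lower. Further loss between 2 and 24 h was called for 955 of the 2418 and recovery for 302, whereas 253 of the 557 higher regions went back down and 76 went further up. Falls between these times were thus called for 39.5% of the lower and 45.4% of the higher regions. The median log2 change of the lower regions went from -0.51 at 2 h to -0.68 at 24 h, and that of the higher regions from 0.34 to 0.15. These regions were chosen by the same 2 h and DMSO libraries, so part of the fall from 0.34 and of the 0.15 left may come from that choice. In the 569 gains chosen in 6211 the 24 h median in 6086 was 0.01. Comparisons in one experiment share DMSO libraries, and simulated unchanged groups gave a correlation of 0.543 between the 2 and 24 h changes against 0.506 observed. The observed covariance of 0.0368 stood beside 0.00753 in those simulations, which shared 0 calls. Within 6211, 895 of the 1010 regions lower at 1 h were also lower at 2 h (49.7), as were 45 of the 90 higher regions in the other direction (1.78), with a covariance of 0.0364 beside 0.00905 simulated. With the DMSO libraries split, 1 for each comparison and both ways round (chosen after the data were seen), the covariance of the 2 and 24 h changes was 0.0288 and 0.0282. The regions lower at both times then numbered 1868 of 2761 and 1521 of 1767 (448.0 and 290.6 for independent lists). Those higher at both numbered 181 of 941 and 97 of 347 (110.0 and 42.8), with 123 and 95 higher at 2 h and lower at 24 h. For gains at 2 and 4 h the split gave 62 of 941 and 55 of 347 (12.7 and 6.48). In 6211 the regions lower at both 1 and 2 h numbered 696 of 1592 and 294 of 326 (50.4 and 17.9), and those higher at both 17 of 967 and 3 of 6 (4.62 and 0.163), with 48 and 0 higher at 1 h and lower at 2 h. Part of the overlaps with all DMSO libraries thus may come from shared controls.

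Lost regions lay near each other along the genome, and so did gained ones. In 6086 at 2 h, 17.1% of the 2418 lower regions had another lower region within 10 kb, against a mean of 5.47% and a maximum of 7.69% over 1000 random sets matched on abundance (permutation p = 0.001, the smallest these draws can give, adjusted p = 0.001 over 9 sets tested). Among the higher regions of this comparison 8.26% had a higher neighbour within 10 kb, against a mean of 1.36% over random sets. The lower regions of 6211 at 2 h had 8.81% against 4.70%. Of 253 neighbouring pairs of called regions in 6086 at 2 h, 98.0% changed in the same direction, against 69.5% with directions shuffled. There were 24 clusters of at least 3 lower regions, holding 80 of the 2418 regions. The cluster with the most was on chromosome 9 from 133336640 to 133356407, where 6 of 7 tested regions fell at 2 h with a median log2 change of -0.57, and all 6 were lower at 24 h. On chromosome 6 from 44621459 to 44636139, 5 of 8 tested regions fell, and 5 of 8 in 6211 as well. On chromosome 16 from 66154478 to 66166169, 4 of 5 fell, with a median log2 change of -0.82 at 2 h and -1.20 at 24 h. On chromosome 9 from 133535974 to 133548966 all 4 tested regions fell, with medians of -0.71 and -0.81. On chromosome 10 from 102645969 to 102661163, 4 of 5 fell at 2 h with a median log2 change of -0.35, but the median was -0.14 at 24 h, when 2 of the 4 were lower, and 1 of 4 tested regions was lower in 6211.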

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

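The tests chosen only after the result was seen were the test of selection by 2 h values, the thinning of libraries, the loess offset and left-out libraries for the comparison of the 2 h effects, and all tests of the chromosome 12 stretch, which was itself found in the data.

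In experiment 6086 the effect at 24 h differed from that at 2 h in 17296 regions, by a direct test of the difference between these times (edgeR). In experiment 6211 the effect at 2 h differed from that at 0.5 h in 581 regions by the same kind of test. With every 6086 library thinned to the lowest total, the 24 h count was 6.06 times the 2 h count, and with the loess offset it was 6.08 times, against 6.17 times in the fit reported.

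Regions higher at 2 h were shared between the experiments less often than lower ones: 24.6% of the 345 higher regions of 6086 were also called in 6211, against 69.4% of the 1606 lower regions. Lower regions matched to the higher ones on the size of the change in 6086 were shared at 42.3% (95% of 1000 draws between 37.4% and 47.8%) in 6211. Matching left a gap of 17.7 percentage points, against 44.7 points for all regions, so smaller effects may account for a large part of it. The match used the same 6086 changes that made the calls. Over all these higher regions the median log2 change was 0.33 in 6086 and 0.28 in 6211, and over the lower ones -0.49 and -0.54. True sizes may thus differ after matching, so the gap left cannot exclude smaller effects as the whole cause. The gaps that follow are for all regions, not matched on size. A trend of the change with abundance is argued against by the loess offset, with which the gap was 45.3 percentage points, and a single DMSO library by a gap of at least 39.0 points without any 1 of the 4. The shares themselves moved with single libraries: without 6211 DMSO library A, 2 h library A or 2 h library B, 7.25%, 15.7% and 5.80% of the higher regions were shared against 46.2%, 49.6% and 48.3% of the lower ones (the smallest gap being 33.9 points), and without 6086 DMSO library B 13.1% against 62.7%. No biological explanation was tested, and what makes gains less often shared at a matched size of change stays open. The test of the difference between the 2 h effects called 0 regions, so no single region was shown to gain in only 1 experiment. That test was checked on 2-fold differences only, which most gains do not reach.

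Gains at 2 h went back by 24 h more often than losses did, but the shares that fell were alike. In the sets chosen in 6211, 43.4% of the gains and 44.4% of the losses fell between 2 and 24 h, while 14.9% and 8.56% rose. The shares going back thus cannot tell a return of gains from a fall common to both sets. Selection of regions for high values at 2 h would give such a return by itself, but in regions chosen in 6211 alone the median gain in 6086 was larger at 2 h than at 24 h by 0.16 on the log2 scale, with an SD between library medians of at most 0.03. No biological explanation was tested, and an effect of the treatment that reverses by 24 h stays open as untested. A technical difference between the 24 h and the earlier libraries, which the labels do not rule out, stays open as well because DMSO was measured at 1 unstated time only.

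Regions higher at 2 h in 6211 lay close together on chromosome 12, with 125 of 806 between 57 and 59 Mb. A single library is argued against as the whole cause of the crowding, since without any 1 of the 4 libraries compared at least 12.2% of the higher regions lay there, but the number there fell to 19 without 2 h library B and to 46 without DMSO library A. Background reads over extra copies of this DNA may account for it, since reads added evenly to all regions would raise weak regions most, and the Spearman correlation of the 2 h change with abundance was -0.60 in the stretch against -0.05 elsewhere. Copy number was not analysed here, and in 6086 the median change over the stretch at 2 h was 0.08 against 0.41 in 6211. In 6086 at 2 h, 17 of the 213 tested regions there were higher and 8 lower. At 0.5 and 1 h in 6211 the median change was 0.13 and -0.07, with 0 regions higher at either time. A treatment effect on the stretch in the cells of 6211 stays open as untested.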

How the results depend on the processing

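The tests chosen only after the data were seen were those with thinned libraries, those with the library letter as a block, those without the chromosome 12 stretch, all alternatives of the followed regions, and the loess offset and left-out libraries for the correlation of the 2 h effects. The named regions kept their direction in all 393 alternative values (33 region-comparisons), and 355 stayed past the threshold. At 24 h all 72 did. The naming rule required both treated libraries on the same side of both DMSO libraries, so the kept direction was largely fixed by the choice of regions. With DESeq2 the counts were 1398, 2103 and 11323 at 2, 4 and 24 h and 9694 for 24 against 2 h in 6086, and 366 and 1341 at 1 and 2 h and 242 for 2 against 0.5 h in 6211. Median-ratio factors in edgeR gave 2979, 4103, 18400 and 2830 at 2, 4 and 24 h of 6086 and 2 h of 6211, so the size factors alone do not account for the DESeq2 counts, and the cause was not tested. With only the groups compared in the fit, counts in 6211 were 10 at 0.5 h, 628 at 1 h and 1245 for 2 against 0.5 h, a fit with fewer libraries to estimate the spread. At 0.5 h the loess offset gave 6, and the cause was not tested. The filter removed 4 regions in 6086 and 0 in 6211, so dropping it tested little.

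Leaving out 1 library assumes that the lone library left varies like the other groups. Counts then ranged from 1560 to 3702 (2 h), 2331 to 4280 (4 h), 14216 to 16382 (24 h) and 12176 to 12851 (24 against 2 h) in 6086. In 6211 they ranged from 0 to 214 (0.5 h), 174 to 2559 (1 h), 1228 to 3356 (2 h) and 109 to 648 (2 against 0.5 h). Why single libraries weigh so much in 6211 was not tested. The correlation of the 2 h effects was 0.702 with regions matched by 1 bp, 0.759 with 80% overlap and 0.626 to 0.697 with 1 library left out. The 24 h median in 6086 of regions lower at 2 h in 6211 was -0.91 with DESeq2, -0.79 with only the groups compared and -0.92 to -0.63 with 1 library left out. For regions higher at 2 h it was 0.072 with DESeq2, 0.041 with library size only, 0.029 with only the groups compared and -0.0034 to 0.087 with 1 library left out. Both sets were chosen in 6211, so leaving out a 6086 library kept them the same, while leaving out a 6211 library changed their membership. The cause of each shift was not tested.

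The replicate numbers of the labels could not be matched to the letters A and B of the tables, so the planned block by number was not run, and the letter was used in its place. With this replicate block by letter (3 residual degrees of freedom) counts were 2761, 3803, 17836 and 16613 at 2, 4, 24 h and 24 against 2 h in 6086, and 11, 1272, 3165 and 709 at 0.5, 1, 2 h and 2 against 0.5 h in 6211. The differences between libraries B and A correlated across regions between groups at -0.14 to 0.15 in 6086 and -0.05 to 0.21 in 6211, so the letters were not shown to pair libraries. Gene lists, promoter and distal regions and sequence motifs were not run.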

Other observations

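The tests at 5 and 50 kb were chosen only after the data were seen, as was the division into chromosomes.

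Chromosomes did not contribute evenly to the changed regions. Of 92 tests (23 chromosomes, 2 directions, 2 and 24 h in 6086), 21 passed Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment. In 3 of the 4 sets chromosome 19 held fewer changed regions than its share of tested regions: 2.19% of the regions lower at 2 h (adjusted p = 3.5e-06), 3.10% of those lower at 24 h (adjusted p = 4.8e-08) and 2.45% of those higher at 24 h (adjusted p = 2.0e-15), against 4.13% of all tested. Of the regions higher at 2 h it held 3.77% (adjusted p = 0.84). Chromosome X held 1.37% of the regions lower at 24 h against 2.09% of all tested (adjusted p = 4.8e-08), and the other 3 sets did not pass there (adjusted p = 0.65, 0.069 and 0.44). Chromosome 1 held 17.4% of the regions higher at 2 h against 10.9% of all tested (adjusted p = 5.3e-05), and chromosome 20 held 39 of the 557, an odds ratio of 2.08 (adjusted p = 0.00085). Neighbouring regions change together, so these p-values describe the lists and are too small as tests of independent regions.

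In 6086 at 2 h, called regions were wider and held more reads in DMSO than regions not called, and these levels are not divided by width, so wider regions hold more reads at the same accessibility. The lower regions had a median width of 390.5 bp and a median of 14.5 CPM in DMSO, and the higher regions 427 bp and 14.0 CPM, against 315 bp and 10.2 CPM for regions not called. In 6211, where most regions had 1 fixed width, the lower regions at 2 h had a median of 22.5 CPM in DMSO, the higher ones 15.4 CPM and those not called 18.3 CPM. At 24 h in 6086 the higher regions had a median of 8.23 CPM in DMSO, below the 10.3 CPM of regions not called, and the lower regions 12.2 CPM. More reads also make a change easier to call, so the differences between these sets may partly be differences in what could be called. That was not tested. The higher regions at 24 h in 6086 and at 2 h in 6211 held fewer reads in DMSO than those not called. The same DMSO libraries helped to choose the regions, which by itself favours low DMSO levels in higher regions and high ones in lower regions. These levels therefore cannot decide the question.

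Relative to random sets of the same size matched on abundance, regions that rose at 2 h in 6211 were the most crowded of the 9 sets tested within 10 kb, with 125 of the 806 in the chromosome 12 stretch: 23.8% had another higher region within 10 kb, against a mean of 1.92% over random sets (permutation p = 0.001, the smallest possible), and 45.2% within 50 kb against 7.35%. For the lower regions of the same comparison the values were 8.81% against 4.70% within 10 kb and 21.1% against 16.4% within 50 kb. The larger sets of 24 h in 6086 had 32.2% (lower) and 25.7% (higher) within 10 kb, against 20.4% and 16.1% in random sets. In 6086 at 2 h, 8.26% of the higher regions had a higher neighbour within 10 kb against 1.36%. At 5 kb, as at 10 and 50 kb, the permutation p was 0.001 or 0.002 for every set.

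Regions changed at 24 h in 6086 were looked up in 6211. Over the 6897 matched regions lower at 24 h, the median log2 change in 6211 was -0.05 at 2 h and 1237 were called lower there, out of 1496 matched regions called lower in all, and over the 3593 matched regions higher at 24 h it was 0.10, with 160 called higher out of 569. The 804 matched regions lower at 1 h in 6211 had a median of -0.81 at 24 h in 6086, where 692 were called lower.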
